A study of Mus musculus with 28 samples.

How the data were processed

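RNA-seq of mouse epidermis was deposited for 28 samples. Per the labels, Kdm6a (also called Utx), an X-linked gene for a histone H3K27 demethylase, was floxed and deleted with a Krt14-Cre transgene. Per the labels' protocols, RNA was extracted with a column kit, selected for poly(A) and made into libraries with a kit that keeps the strand. The labels give 6 female controls, 3 heterozygous females, 7 conditional knockout (cKO) females, 6 male controls and 6 male cKO animals. All controls were labelled Cre-negative, and male control replicate 3 carried no floxed allele. Replicate numbers follow the order of the samples within each label, because the labels carry none. Nothing in the labels states that replicates came from separate animals. The ages, young and aged, come only from the titles of the deposited tables.

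The authors deposited 4 tables of normalized signal values per library and gene, for young females, young males, aged females and aged males, and 5 comparison tables. The deposited signal values are not whole counts: within each library most low values are multiples of a library-specific step, as counts divided by a size factor are. The share of low values within a tolerance of 0.1 step of a whole multiple, up to 20 steps, was 54.1% to 88.4%. Each comparison table gives, per the file headers, mean signal values, a log2 fold change and its standard error, a test score, a p-value and an adjusted p-value that the authors computed. The submitters' processing notes name STAR, DESeq2 and the builds GRCm38 and mm10, without versions or roles. The counting program, the gene annotation and any filter are not stated. The comparison tables as held here stop in alphabetical order at Olfr577, with 16370 genes each, and genes after it were not analysed here from those tables. No per-library values were held for the 3 heterozygous libraries, so the heterozygous comparison is described from the authors' deposited table without a test of its own, and a direct test of cKO against heterozygous females was not run.

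Each table held 24972 genes. Of these, 26 names in every table had been turned into dates and were left out, which left 24946 symbols, of which 24417 (97.9%) matched the GENCODE mouse annotation of GRCm38 used for coordinates. Reads per library, approximated as the sum of values divided by the step, ranged from 15.8 to 34.4 M, the sums of normalized values from 19.3 to 31.1 M, and genes above 0 from 16405 to 17923. Between replicates of a group, among genes with a mean of at least 500, the smallest SD of a log2 ratio was 0.187, against at most 0.0609 from counting alone. Read counting error is not given per value, because counts were not used here.

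The 4 tables were scaled separately, so every test was made within 1 table. A quasi-likelihood test had been chosen for whole counts and another test for normalized values, and the latter was used: limma (version 3.58.1, in R 4.3.3) with an intensity trend on log2(value + 1), for genes with a value of at least 10 in at least as many libraries as the smaller group, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. All adjusted p-values below are from limma unless the authors' deposited table is named. Kdm6a was also compared with an exact two-sided permutation test of the log2 values. The differences of the cKO effect between 2 tables were tested with a z test on the log2 changes and their standard errors. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and beside it with an estimated correlation and with fry. Overlaps of calls were compared with those of independent lists by one-sided Fisher exact tests.

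The grouping, the tests, the gene lists, the rule for naming genes and the first alternatives below were written before the data were examined. The rule names Kdm6a and 7 genes that check sex. For each comparison it then names the 10 largest rises and falls (5 for aged or heterozygous females) among called genes whose groups do not overlap and whose mean log2 CPM is at least 0, leaving out predicted genes. It also names up to 4 members per list and 5 genes per direction for a difference. Some genes that the rule names are not reported here. The 26 lists were cornified envelope, suprabasal differentiation, basal layer, retinoid pathway, lipoxygenase and ferroptosis, barrier lipid, sebaceous gland, cholesterol synthesis, cell cycle, wound and stress keratinocyte, hair shaft and matrix, hair follicle stem cell, interferon response, inflammatory cytokine, p53 and senescence, H3K4 and H3K27 enzyme, fibroblast, endothelium, skeletal muscle, melanocyte, T cell, Langerhans and myeloid, adipocyte, erythrocyte, mitochondrial transcript, and immediate early and heat shock. The mitochondrial list had no tested members. After the data were seen, the pseudocount in log2 CPM for the naming rule was set to that of the test, because a value near 0 had dropped any gene with a library at 0. Gh entered the named genes through that change. The set of genes that escape X inactivation was widened from 3 to 9 after the first 3, all lower, had been seen, and the simulated unchanged tables for the z test were changed from pairs within a table to the pairs tested. Further tests on the labels of aged males were run and are not reported here.

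The gene test was tried on simulated values with 100 genes changed by 1 log2 unit and 100 by 2. It recovered 61 and 93 of them in data made like the young female table, 38 and 82 for young males, 27 and 65 for aged females, and 38 and 58 for aged males. In that order, 11 of 165, 4 of 124, 1 of 93 and 3 of 99 calls were false. It made 0 calls in unchanged data. The simulated libraries were independent of each other, unlike real libraries of the same series of library numbers, so this does not cover that structure. For the z test, simulated unchanged pairs of tables gave 39 to 88 calls between young females and young males, 120 to 189 between young and aged females, and 77 to 119 between young and aged males, so its calls are given beside those numbers and beside a t test with Satterthwaite degrees of freedom, which gave at most 3, 5 and 1. With the block for library numbers, tables simulated with the series means and the spread of that fit gave 187 to 266, 498 to 579 and 445 to 517 z calls, and 0 to 8, 7 to 38 and 0 to 2 t calls.

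Alternatives chosen beforehand were a pseudocount of 0.1, no filter on low values, leaving out each library in turn, and a block for the series of library numbers, read from library names as numbers within 10 of each other. Libraries of the same series deviated together: the correlation of deviations from the group means was 0.46 to 0.66 within series and -0.58 to 0.53 between series in young females, 0.49 to 0.67 and -0.51 to 0.08 in young males, 0.31 and -0.31 in aged females, and 0.34 to 0.72 and -0.54 to 0.26 in aged males. Deviations from a group mean cancel within the group, which by itself lowers the values between series. With 2 libraries a group, the 2 aged female values are the same value with opposite signs. The labels do not state what a series is, so the fit without the block is the reported one. Quantile normalization, median-of-ratios rescaling, robust moderation, the Satterthwaite test with and without the block, the exact reading of the series, and a fit without 3 aged male libraries were added after the data were seen.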

Results

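The deposited data are poly(A) RNA-seq profiles of mouse epidermis in which Kdm6a was deleted with Krt14-Cre. Per-library values were available for 4 control and 5 cKO young females, 3 control and 3 cKO young males, 2 control and 2 cKO aged females, and 3 control and 3 cKO aged males. Libraries held about 15.8 to 34.4 M reads. Values are normalized read counts with SD over libraries, and changes are log2 fold changes of cKO over control with standard errors (SE).

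Kdm6a, which lies on chromosome X from 18162575 to 18279936 (GRCm38), was lower in every library labelled cKO than in every control of its table, except in aged males. In young females it fell from 1445 ± 171 (SD, n = 4) in controls to 1019 ± 106 (SD, n = 5) in cKO, a log2 change of -0.50 (SE 0.11, adjusted p = 0.0300). The exact permutation p was 0.00794, the smallest that the 126 splits allow. In young males it was 966 ± 196 in controls and 502 ± 61.7 in cKO, a log2 change of -0.93 that did not pass over all genes (adjusted p = 0.902, exact p = 0.1, the smallest possible with 3 against 3). The authors' deposited table for young males did call Kdm6a (-0.945, the authors' adjusted p = 0.0106). In aged females it fell from 3109 ± 364 to 1336 ± 52.4, a log2 change of -1.21 (adjusted p = 0.0258, exact p = 0.333, the smallest possible with 2 against 2). Both aged cKO female libraries also lacked Xist (17.1 and 14.4), so this fall cannot be told apart from another difference of the X chromosome. In aged males the libraries labelled control had 1090, 1224 and 1511, and those labelled cKO had 584, 1322 and 673 in replicates 4, 5 and 6 (log2 change -0.65, exact p = 0.3). Replicate 5 labelled cKO was thus at the level of the controls. These gene-level values include reads outside the deleted part, which the labels do not specify, so they measure the remaining RNA of the gene and not the extent of deletion. The call was lost in young females without control 2, 3 or 4 or without cKO 1, 2, 3 or 5 (adjusted p 0.0548 to 0.0878) or with quantile normalization (0.051), and in aged females without any 1 of the 4 libraries (adjusted p 0.0585 to 0.104) or without the filter (0.134).

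The Y-linked genes Uty, Kdm5d, Ddx3y and Eif2s3y were at most 3.89 in every female library with deposited values and at least 215 in every male library. Kdm5c, Ddx3x and Eif2s3x, X-linked relatives of these genes, did not pass the test in any of the 4 comparisons (smallest adjusted p = 0.0783, Eif2s3x in aged females).

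**Figure D1:**
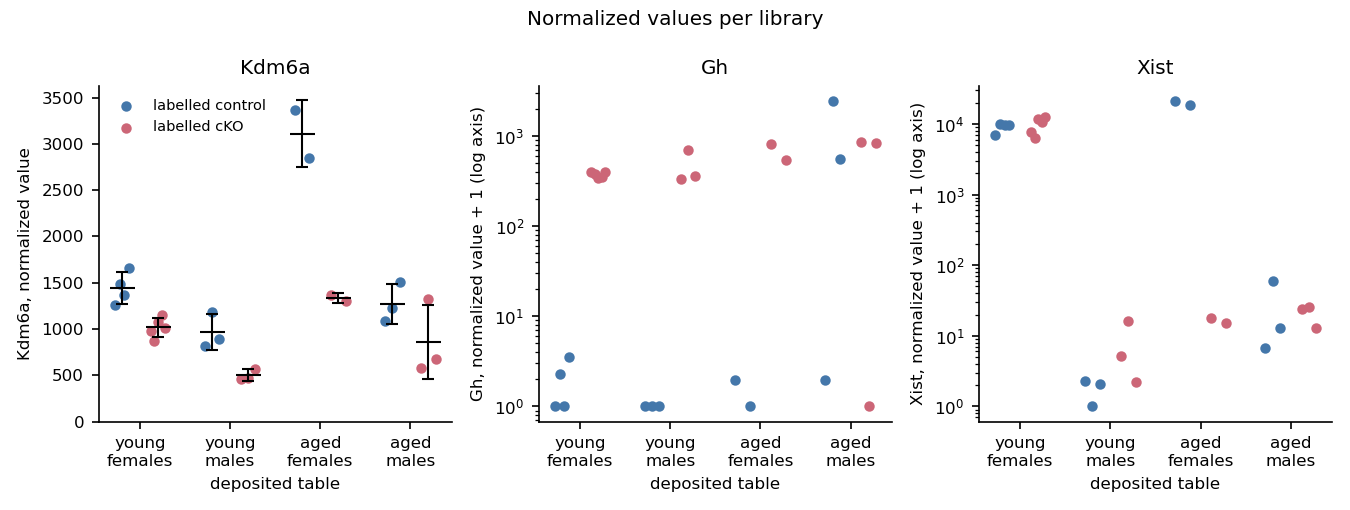
Normalized values per library of Kdm6a (linear axis), Gh and Xist (log axes, value + 1) in the 4 tables, with mean and SD for Kdm6a. Kdm6a of aged male replicate 5 labelled cKO is 1322, Gh of aged male control replicates 5 and 6 is 2443 and 559, and Xist of the 2 aged cKO females is 17.1 and 14.4.

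In young females, the comparison asks how the epidermis changes when both copies of Kdm6a are lost. Several genes known to be induced by interferon were among those that rose: Ifi44 rose from 17.5 ± 9.17 to 187 ± 81.1 (log2 change 3.39, SE 0.38, adjusted p = 0.00104), Ifi27l2a from 143.3 ± 24.4 to 1213 ± 453 (3.03, SE 0.22, adjusted p = 7.31e-05), Oas2 from 79.3 ± 20.1 to 483 ± 167 (2.56, adjusted p = 6.84e-04), and Ifit1 from 78.3 ± 45.1 to 393 ± 165 (2.38, adjusted p = 0.0108). Among genes of keratinocyte differentiation, the suprabasal keratin Krt1 rose from 37748 ± 4979 to 90255 ± 16224 (log2 change 1.25, adjusted p = 0.00322) and the envelope precursor Ivl by 1.33 (adjusted p = 0.00834). Their lists did not move with them. Krt10 was 0.06 (adjusted p = 0.925), and the suprabasal differentiation list had a median of 0.03, with 16 of 29 members above 0. The cornified envelope list had a median of -0.22, with 14 of 37 above 0. The transglutaminase gene Tgm7 fell from 478 ± 97.3 to 52.6 ± 19.4 (-3.21, adjusted p = 1.52e-04) and the transcription factor gene Sox15 from 89.2 ± 15.9 to 9.75 ± 5.50 (-3.25, adjusted p = 0.00284). Gpha2, a glycoprotein hormone subunit gene, fell from 379 ± 167 to 22.9 ± 8.29 (-3.95, adjusted p = 1.84e-04) and the zinc transporter gene Slc39a2 from 563 ± 45.0 to 56.8 ± 19.2 (-3.35, adjusted p = 6.21e-05).

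The largest rise was that of Gh, the growth hormone gene on chromosome 11, which was 0 to 2.58 in controls and 342 to 405 in cKO (adjusted p = 7.90e-06). Gh was also high (2443 and 559) in the aged male libraries labelled control 5 and 6, whose Kdm6a was not low. Its rise therefore need not follow from loss of Kdm6a, and it is not separated from the presence of the Cre transgene, which every control lacked by label. The ranks hold among called genes with a mean log2 CPM of at least 0, no overlap between the groups and no predicted name. These limits leave out Efhc2 (3.98), Gria3 (3.30), S100a8 (2.76) and Hba-a2. Gh was followed by Ifi44, Ifi27l2a, Akr1c13 (2.74), Oas2, Cemip (2.50), Ifit1, Shank3 (2.34), Apol9b (2.27) and Ntrk3 (2.25). The largest falls were those of Gpha2, Acoxl (-3.37), Slc39a2, Sox15, Tgm7, Ccdc27 (-3.12), Sardh (-2.90), Xpnpep2 (-2.89), the carbonyl reductase gene Cbr2 (-2.82) and Cyp2w1 (-2.71). Slc39a2 overlaps the annotated gene Mettl17, and the counting is not stated, so its value is uncertain in that respect. It also varied within groups in young males (87.7, 78.9 and 555 in controls, 402, 524 and 101 in cKO), and its log2 change in aged females was 0.07. Its fall in young females therefore need not follow from loss of Kdm6a. In total 547 of 13898 tested genes passed the threshold, 214 rose and 333 fell, and all 547 had the same sign in every series of library numbers. In 507 of them the values of the 2 groups did not overlap. The authors' deposited table, to Olfr577, called 667 genes, including 351 of the 353 called here that it could test.

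By list, the interferon response had 7 risen members of 22, with Oas1a (1.82) among them, 13 adjusted over the list alone, all 22 above 0, and a median log2 change of 1.19 (camera adjusted p = 3.65e-11), but adjusted p = 0.649 with an estimated correlation. Its mean change was 1.31, 1.59 and 0.46 within the 3 series of library numbers. The Langerhans and myeloid list had 1 risen member, Csf1r (0.78), 7 adjusted over the list alone, and a median of 0.41 (adjusted p = 5.16e-05, and 0.649 with an estimated correlation). The erythrocyte list fell (median -1.38, adjusted p = 0.00460, and 0.253 with an estimated correlation). Its fallen members Hba-a1 and Hba-a2 are near-identical copies and are uncertain, and Hba-a2 was listed at 0 in all 5 cKO libraries. The basal layer list fell, with a median of -0.27, the cadherin gene Cdh3 among its fallen members (-0.63, adjusted p = 0.0176), 2 members fallen over all genes and 3 fallen adjusted over the list alone (adjusted p = 0.0494, and 0.961 with an estimated correlation). The basal call was lost without control 3 (0.177) or 4 (0.148) and without cKO 1 (0.135), 2 (0.154) or 5 (0.0605), and with quantile normalization (0.127). With the block for library numbers the wound and stress keratinocyte (adjusted p = 0.0496) and fibroblast lists (0.0107) were also called up, but both had an adjusted p of 0.641 with an estimated correlation. The other 21 lists tested were not called (adjusted p 0.0656 to 0.994). They hold the called genes Krt1, Skint3 (0.56) and Cst6 (0.53) of suprabasal differentiation, Ivl of the cornified envelope, and Crabp2 (-0.94) and Rarres1 (-0.87) of the retinoid pathway. They also hold Aloxe3 (-0.47) of lipoxygenase and ferroptosis, S100a8 (2.76) of wound and stress keratinocyte, and Hoxc13 (-0.63), Krt32 (-0.80) and Tchh (1.0) of hair shaft and matrix. The remaining called members are Il33 (-0.71) of inflammatory cytokine, Ccng1 (0.48) of p53 and senescence, Fn1 (1.92, adjusted p = 0.00907) of fibroblast, and Kit (1.66) of melanocyte. The barrier lipid list had 2 members risen and 3 fallen, and the hair follicle stem cell list 1 risen, only when adjusted over the list alone. The lists sebaceous gland, cell cycle, H3K4 and H3K27 enzyme, endothelium, skeletal muscle, T cell, adipocyte, and immediate early and heat shock had 0 called members in limma by either adjustment.

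With the block for library numbers 2011 genes passed, among them all 547, and without 1 library the count was 274 to 435. It moved by more than 1.5 times without control 1 (274), 2 (307) or 3 (326) and without cKO 3 (337), 4 (337) or 5 (343), and of the 43 named genes called, 26 kept the call without any 1 library. Among the 17 that lost it at least once were Kdm6a, Cemip, Skint3, Cst6, Cdh3, Crabp2, Rarres1, Aloxe3, S100a8, Krt32, Tchh, Il33, Ccng1, Kit, Csf1r and Hba-a1, with 12, 13, 10 and 10 lost without controls 1 to 4 and 7, 8, 9, 9 and 10 without cKO 1 to 5. The calls of Rarres1, S100a8 and Hba-a1 were also lost without the filter and with quantile normalization, and those of Cst6 and Kit without the filter.

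**Figure D2:**
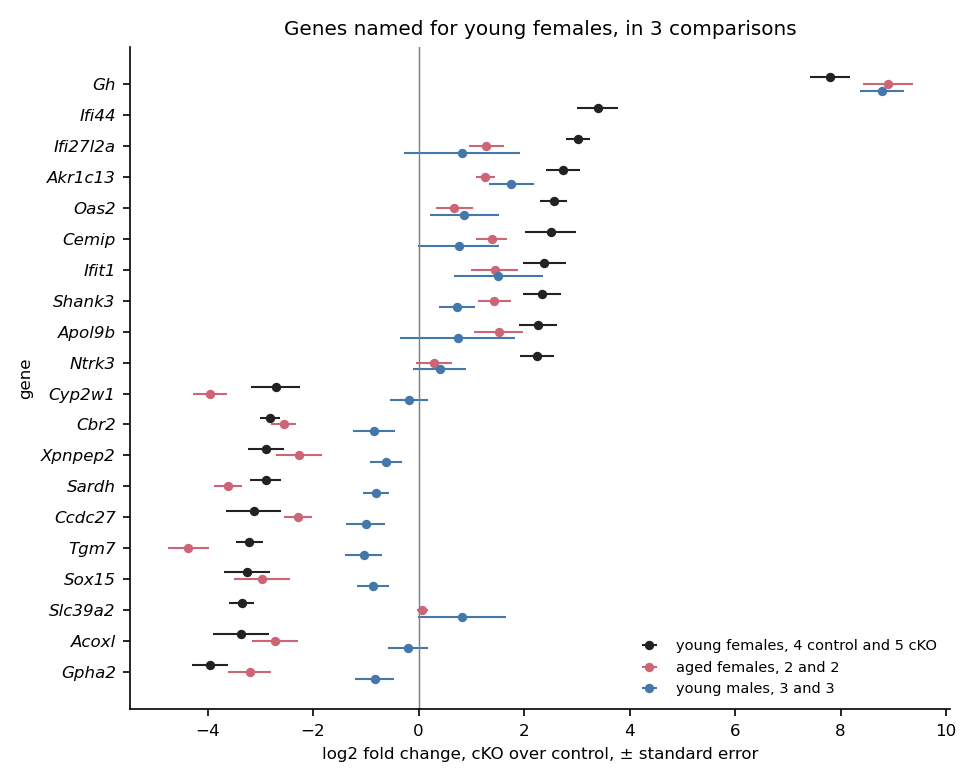
Log2 fold change of cKO over control, with standard error, for the 10 largest rises and 10 largest falls of young females among called genes with a mean log2 CPM of at least 0 and no overlap between the groups, in young females (4 and 5 libraries), aged females (2 and 2) and young males (3 and 3). A gene has no point where it did not pass the filter on low values. Slc39a2 is -3.35 in young females and 0.07 in aged females.

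Heterozygous young females, which keep 1 intact copy of Kdm6a, are described from the authors' deposited table. Some genes known to be induced by interferon rose there, with log2 changes of 3.34 for Ifi44, 2.51 for Oas2, 2.32 for Ifi27l2a and 1.78 for Oas1a, while Ifit1 (1.94), Irf7 (1.15), Isg15 (1.23) and Oasl2 (1.34) did not pass in the authors' deposited table (adjusted p at least 0.502). Gh rose from a mean of 1.58 to 607 (log2 change 8.58). In the authors' deposited table for young cKO females the same genes were 3.44, 2.61, 3.08, 1.81 and 8.53, so Ifi44, Oas2, Oas1a and Gh were close in the 2 genotypes. Cyp2g1 (2.38, and 1.41 in cKO) and Akr1c18 (1.31, and 0.85 in cKO) also rose. The only gene that fell was BC021767 (-0.84). The authors' deposited table called 25 genes, 24 up and 1 down, and Kdm6a was -0.27 (the authors' adjusted p = 1.0). Of 150 genes risen in young cKO females and listed there, all 150 were above 0, with a median ratio of the heterozygous to the cKO change of 0.629 (95% bootstrap interval 0.592 to 0.688). Of 202 fallen genes, 196 were below 0, with a median ratio of 0.390 (0.356 to 0.404). Both comparisons draw on shared control libraries, and the deposited means imply 2 controls in the heterozygous one, so these ratios do not come from independent samples. The genes were chosen by their change in the cKO libraries, which by itself lowers the ratios. The bootstrap resampled genes, so its intervals do not cover the variation between libraries.

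**Figure D3:**
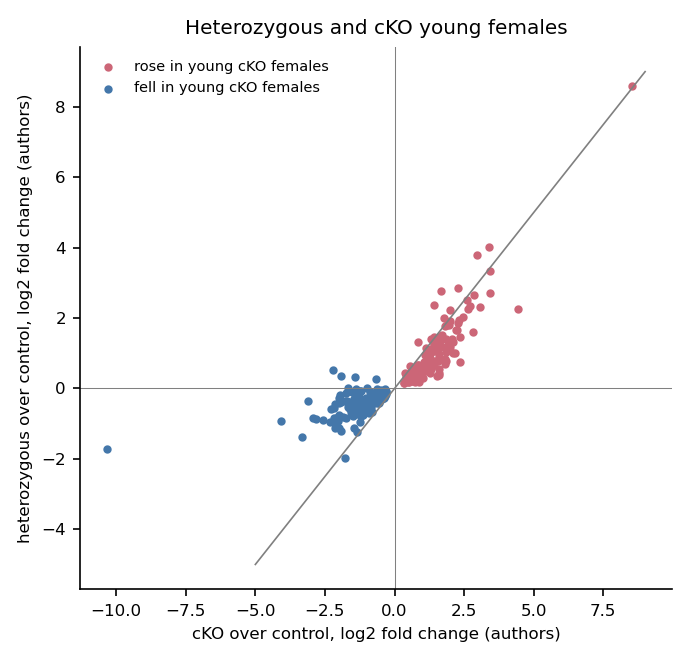
Log2 fold changes in the authors' deposited tables for genes called in young cKO females, in cKO (horizontal) and heterozygous (vertical) young females, with the line of equal change. Risen genes lie nearer to the line (median ratio 0.629) than fallen genes (0.390).

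In young males, which lose their only copy of Kdm6a and keep the Y-linked relative Uty, 2 genes passed the threshold, and both rose. Gh was listed at 0 in all 3 controls and at 331, 700 and 364 in the cKO libraries (adjusted p = 3.05e-04). Akr1c18, a hydroxysteroid dehydrogenase gene, rose from 129 ± 21.4 to 737 ± 133 (log2 change 2.50, SE 0.21, adjusted p = 0.0117). All controls were labelled Cre-negative, so neither rise is separated from an effect of Cre. In aged males both genes were high in libraries labelled control 5 and 6 (Akr1c18 663 and 964), whose Kdm6a was 1224 and 1511. Both were low in the library labelled cKO 5 (Akr1c18 42.5, Gh 0). The other genes called in young females were not called here. Of the 197 genes risen in young females and tested here, Gh and Akr1c18 included, 175 were above 0, with a median ratio to the female change of 0.52. Of 330 fallen genes 302 were below 0, with a median ratio of 0.30. Of 13743 genes, 320 had an unadjusted p below the threshold. The authors' deposited table called 14 genes, including both, 11 up and 3 down, with Kdm6a among the 3. With the block 7 genes passed, and the call of Akr1c18 was lost without control 3 (adjusted p = 0.0547), which carried no floxed allele, without cKO 1 (0.104) or without cKO 2 (0.10).

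Camera called 11 lists in young males, 3 up and 8 down, with 0 called members in limma, and none with an estimated correlation (smallest adjusted p = 0.0693). The cornified envelope list had a median of -0.40 (adjusted p = 7.70e-13, and 0.0693 with an estimated correlation), the skeletal muscle list -2.50 (3.73e-16, and 0.488) and the hair follicle stem cell list 0.31 (4.70e-05, and 0.383), and these 3 calls held without any 1 library. The muscle list was 3.59 above the table mean in control 3 and -2.86 in cKO 3, so muscle transcripts differed between these libraries. The interferon response list had a median of 0.54 (adjusted p = 6.55e-06, and 0.705 with an estimated correlation), with means of 1.62, 0.30 and -0.11 within the 3 series, and was not called without cKO 1 (0.934). The other 7 called lists, suprabasal differentiation (-0.07), sebaceous gland (0.22), wound and stress keratinocyte (-0.37), inflammatory cytokine (-0.25), endothelium (-0.59), T cell (-0.17), and Langerhans and myeloid (-0.23), each lost the call without at least 1 library and had an adjusted p of at least 0.522 with an estimated correlation. Suprabasal differentiation lost it without control 1 (0.239), control 3 (0.255) or cKO 2 (0.704) or with quantile normalization (0.253), sebaceous gland without cKO 2 (0.230), and wound and stress keratinocyte without control 3 (0.620, with its direction turned) or cKO 1 (0.420). Inflammatory cytokine lost it without control 2 (0.173), control 3 (0.406) or cKO 1 (0.256), endothelium without control 1 (0.810), cKO 2 (0.156) or cKO 3 (0.328), T cell without control 2 (0.272) or cKO 3 (0.569), and Langerhans and myeloid without control 1 (0.0804), control 2 (0.605) or cKO 3 (0.930, with its direction turned).

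In aged females, Xist, the RNA that silences 1 X chromosome in female cells, was 20923 and 18431 in the controls and 17.1 and 14.4 in the cKO libraries (log2 change -10.20, SE 0.15, adjusted p = 4.72e-06). Tgm7 fell from 932 ± 87.3 to 48.3 ± 28 (-4.37, adjusted p = 0.0247) and Cyp2w1 from 315 ± 2.67 to 20.1 ± 7.88 (-3.96, adjusted p = 0.0223), as in young females. The late envelope genes Lce1e (-2.41, adjusted p = 0.0335) and Lce1d (-1.77, adjusted p = 0.0480), the sterol acyltransferase gene Soat1 (-1.01) and the retinoic acid binding protein gene Crabp2 (-1.13) fell. Gh (0.955 and 0 in controls, 820 and 541 in cKO, adjusted p = 0.00718), the X-linked gene Efhc2 (4.48 ± 3.62 to 212 ± 51.6, log2 change 5.43), Wfdc18 (3.73) and the calgranulin gene S100a9 (18.6 ± 0.777 to 116 ± 38.6, 2.54) rose. In total 98 of 14652 genes passed, 25 rose and 73 fell. All 98 were without overlap between the groups, which with 2 against 2 libraries nearly follows from the call and adds no support. The authors' deposited table called 417 (135 up and 282 down), including the 58 of the 98 that it could test.

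Further named genes were Smco3 (-3.65), Fn1 (1.70), Sparc (-0.94) and Adipoq (-3.03). Snrpn rose (4.35) where its overlapping partner Snurf went from 144 and 142 to 0 and 0, and Xntrpc fell (-3.89) where its overlapping partner Trpc2 went from 0 and 0 to 106 and 123, so both are uncertain as changes of expression. With the block 431 genes passed, without the filter 1, and without control 5 30, control 6 22, cKO 6 14 and cKO 7 13. Among the 19 named genes called, only Xist kept the call without any 1 library and without the filter, with 11, 15, 15 and 16 lost without control 5, control 6, cKO 6 and cKO 7.

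Camera called 12 lists in aged females, 4 up and 8 down, and none with an estimated correlation (smallest adjusted p = 0.626). The cholesterol synthesis list fell (median -0.54, 15 of 20 members fallen adjusted over the list alone and 1 over all genes, adjusted p = 3.18e-11, and 0.626 with an estimated correlation), as did the cornified envelope (-0.44, 16 members and 2, adjusted p = 2.51e-07, and 0.626), hair shaft and matrix (-2.60, 10 and 0, adjusted p = 1.13e-09, and 0.626) and adipocyte lists (-1.63, 4 and 1, adjusted p = 4.05e-06, and 0.626). The interferon response list rose (0.68, 12 members risen and 1 fallen adjusted over the list alone and 0 over all genes, adjusted p = 5.64e-08, and 0.626). These 5 calls held without any 1 library. The lists barrier lipid (-0.20), sebaceous gland (-0.52), wound and stress keratinocyte (0.40), endothelium (-0.65), skeletal muscle (-1.43), melanocyte (0.50) and T cell (0.23) were called but lost the call without at least 1 library, and their adjusted p was at least 0.626 with an estimated correlation. Without control 5 the calls of wound and stress keratinocyte (0.587), endothelium (0.321), melanocyte (0.0504) and T cell (0.287) were lost, and without control 6 those of barrier lipid (0.107), skeletal muscle (0.941) and melanocyte (0.0778). Without cKO 6 those of barrier lipid (0.0907), sebaceous gland (0.0543) and skeletal muscle (0.0987, with its direction turned) were lost, and without cKO 7 those of wound and stress keratinocyte (0.248), endothelium (0.366) and melanocyte (0.301). Quantile normalization ended the calls of melanocyte and T cell (both 0.0727), and with the block cell cycle (0.0371) and Langerhans and myeloid (0.0350) were also called up, both with an adjusted p of 0.53 with an estimated correlation.

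In aged males the labels and 2 transcripts did not match in 3 libraries. Gh was 0.948, 2443 and 559 in the libraries labelled control 4, 5 and 6, and 866, 0 and 843 in those labelled cKO 4, 5 and 6, while it was at most 2.58 in every control and at least 331 in every cKO library of the other tables. Kdm6a was 1322 in the library labelled cKO 5. Akr1c18, which rose in young males, was 36.8, 663 and 964 in the libraries labelled control and 835, 42.5 and 1317 in those labelled cKO, and Cyp2g1 was 4.75, 1825 and 326 and then 2145, 2.12 and 1375. Both were thus low in the 2 libraries with Gh below 1, and high in control 5 and 6, whose Kdm6a was 1224 and 1511. Directions between the labelled groups are therefore given with that doubt. Of 14330 genes, 2 passed the threshold (119 at an unadjusted p), Snurf up and Snrpn down in libraries labelled cKO. These 2 overlap, and each library had its reads in only 1 of them, so they are uncertain. The authors' deposited table called 1 gene, down. Without the 3 libraries 58 genes passed, 32 up and 26 down, with 1 library labelled control and 2 labelled cKO. The 3 were left out by their Gh values, so Gh is among the 58 by construction, and most of the falls are genes of skeletal muscle, such as Acta1, Myh1 and Ttn, which were high in that 1 control. Without 1 library 0 or 1 passed (1 without control 4 or 6, and 0 without control 5 or cKO 4, 5 or 6).

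Camera called 7 lists between the labelled groups of aged males, with 0 called members in limma, and none with an estimated correlation (smallest adjusted p = 0.152). The sebaceous gland list had a median of 0.26 (adjusted p = 1.72e-06, and 0.152 with an estimated correlation) and held without any 1 library. The skeletal muscle list had a median of -1.73 (2.26e-07, and 0.642 with an estimated correlation) and was not called without control 4 (0.415), in which it was 4.30 above the table mean. The lists cornified envelope (0.22), wound and stress keratinocyte (0.49), hair shaft and matrix (0.48), melanocyte (0.55) and adipocyte (0.98) were up, with an adjusted p of 0.642 with an estimated correlation, and each lost the call without at least 1 library. Without control 4 these were the cornified envelope (0.113, with its direction turned), wound and stress keratinocyte (0.690, turned) and hair shaft and matrix (0.598). Without control 5 they were the cornified envelope (0.268), wound and stress keratinocyte (0.0576), hair shaft and matrix (0.848) and melanocyte (0.289), and without control 6 adipocyte (0.393). Without cKO 4 it was wound and stress keratinocyte (0.0848), without cKO 5 adipocyte (0.900), and without cKO 6 the cornified envelope (0.172), wound and stress keratinocyte (0.221), hair shaft and matrix (0.0929, turned) and melanocyte (0.530). With the block suprabasal differentiation (0.0445), retinoid pathway (0.00913) and fibroblast (0.0445) were also called up, with an adjusted p of at least 0.672 with an estimated correlation.

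**Figure D4:**
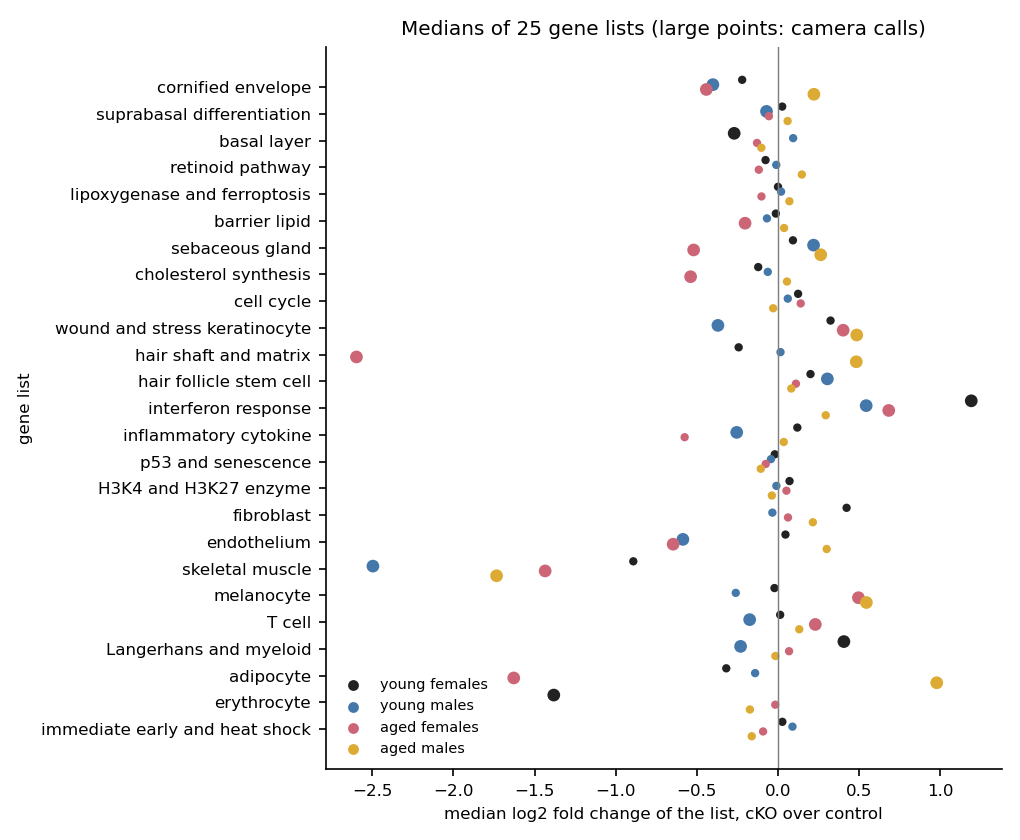
Median log2 fold change of cKO over control for 25 gene lists in the 4 comparisons, with large points where camera called the list at its preset correlation. The interferon response is at 1.19 in young females, 0.54 in young males and 0.68 in aged females. No list was called with an estimated correlation.

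The young and aged female comparisons hold separate libraries, and 64 genes were called in the same direction in both, against 2.07 for independent lists. The number was 0 without the filter, 39 with quantile normalization and 295 with the block. Of the 64, 12 rose (0.352 for independent lists, one-sided Fisher exact p = 1.40e-16) and 52 fell (1.71, p = 7.81e-70, Fisher exact), with Gh and Fn1 among the risen genes and Tgm7, Cyp2w1 and Crabp2 among the fallen. Genes are not independent replicates, so these p-values describe the overlap only. The rise of Gh in both comparisons is not separated from the presence of Cre, which the controls lacked by label. Of the genes called in young females, 206 of 211 risen and 329 of 333 fallen ones had the same sign in aged females, with median ratios of 0.71 and 0.86, and in aged males, with the labels as given, 163 of 206 and 241 of 332, with 0.18 and 0.13.

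Whether the cKO effect differs between sexes or ages was tested on the difference itself. Between young females and young males, Gpha2 was -3.95 and -0.83, Sardh -2.90 and -0.81, Krt1 1.25 and -0.05, and Fn1 1.92 and 0.44, while the cytochrome gene Cyp2g1 was 1.44 and 6.72 and Carns1 0.22 and 2.81. The z test called 45 of 13535 genes, 42 of them called in young females and 35 with the same sign in both sexes, which lies within the 39 to 88 calls of simulated unchanged tables. The t test with Satterthwaite degrees of freedom called 0, with 415 genes at an unadjusted p (566 for the z test). With the block for library numbers the z test called 384 genes, against 187 to 266 in simulated unchanged tables, and the t test 120, 24 with a higher and 96 with a lower log2 change in females, against 0 to 8, with Gpha2, Sardh, Krt1, Cyp2g1 and Carns1 among them. Whether single genes differ between the sexes thus depends on the block, and without male control 1 the z test called 129 and without male cKO 2 20.

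Between young and aged females, Xist was 0.07 and -10.20 and Slc39a2 -3.35 and 0.07, and these 2 and Trpc2 were called by both tests (Satterthwaite adjusted p = 5.25e-14 for Xist, 1.19e-05 for Slc39a2 and 0.0442 for Trpc2). Trpc2 and Slc39a2 overlap other genes and are uncertain, and Slc39a2 also differed within groups: it was 87.7, 78.9 and 555 in young male controls and 402, 524 and 101 in young male cKO, and 926, 162 and 727 in aged male libraries labelled control. The z test called 15 genes of 13792 and the t test 3, against 120 to 189 and at most 5 in simulated unchanged tables, so neither count exceeds what unchanged tables gave. The z count was 30, 47 and 31 without controls 4, 5 and 6, 31 and 71 without cKO 6 and 7, and 227 with the block (498 to 579 in simulated unchanged tables), where the t test called 7 (7 to 38). Between young and aged males the z test called 0 of 13639 genes (216 at an unadjusted p), as did the t test (132). With the block the z test called 43 (445 to 517 in simulated unchanged tables) and the t test 1, the uncertain Snurf (0 to 2). The z test called 2 without male cKO 3 or control 6, and 1 without cKO 6. Because 3 aged male libraries go against their label, these counts do not show whether the cKO effect differs with age in males.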

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

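The tests in this part on heterozygous females, on the aged male labels and on Xist, the t tests of the differences, and the splits within series, were chosen after the results were seen.

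Over genes changed in young cKO females, the median change in heterozygous females was in the same direction and smaller, though some genes, such as Gh, Cyp2g1 and Akr1c18, changed there as much or more. Shared control libraries raise such a match by themselves, but the covariance of the 2 sets of log2 changes was 0.128, against a mean of 0.0510 and a highest value of 0.0652 in simulated unchanged groups sharing 2 controls, which argues against them as the whole source. An effect of the Cre transgene alone, equal in both genotypes, would give a ratio near 1, and the median over fallen genes was 0.390. These genes were chosen by their change in the same cKO libraries, which by itself lowers the ratio to an extent not measured. With that limit, the ratio argues against such an effect as the whole source for those genes. Over risen genes the median was 0.629, but Gh, Ifi44, Oas2 and Oas1a had nearly equal changes in both genotypes, as such an effect predicts, and every control was labelled Cre-negative, so for such genes it stays open. A dose effect of the deleted allele is the biological difference that the design names, and it was not tested separately from Cre.

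In aged males, 3 libraries had Kdm6a or Gh values against their label. A swap between the groups needs a library labelled control with low Kdm6a, and the lowest of these was 1089.74, against 673.268 as the highest of the other 2 libraries labelled cKO, which argues against it. For the library labelled cKO 5, an animal without Cre could account for its Kdm6a of 1322.06 and Gh of 0, and this stays open. For the libraries labelled control 5 and 6, Cre-positive animals with Kdm6a not deleted could account for Gh of 2443 and 559 with Kdm6a of at least 1223.78, and this stays open as well. A biological change with age was not tested.

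The 2 aged cKO females lacked Xist. Male animals would carry Y-linked RNA, and the highest value of 4 Y-linked genes was 2.07, which argues against them. Loss of Kdm6a itself, without another difference, would lower Xist in young cKO females too, where its log2 change was 0.074, which argues against it apart from age. For a single X chromosome in both animals, the first 3 genes looked at that are known to escape X inactivation were Kdm5c, Ddx3x and Eif2s3x. All 3 were lower in both libraries than in both controls. Their log2 changes were -0.43, -0.12 and -0.52, against 0.17, 0.02 and -0.09 in young females. The set was then widened to 9 such genes, of which 4, Jpx included, were lower in both libraries. With that split and 2 libraries, a single X chromosome cannot be told apart from other sources. The other X-linked genes had a median log2 change of 0.09 over 476 genes, against 0.00 for autosomal genes.

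Other splits of the libraries gave a count as large in 3 of 100 splits for young females, the real one included (547, highest other 1930). That split, with control 4 and cKO 3, 4 and 5 against the rest, has all 4 libraries of series 1 on one side, so a structure of the samples that follows the series of library numbers is larger than the labelled difference in some splits. For young males it was 1 of 10 (2, highest other 1) and for aged males 3 of 10 (2, highest other 14), too few splits for a share under 0.05. For the difference between young females and young males 12 of 100 joint splits gave as many (45, highest other 1640), without regard to the series. With the block and splits within the series, in the t test, it was 2 of 100 (120, highest other 3.9 times as many), and that highest split turns the labels of all young females but cKO 3, so it still holds most of the female difference. Between young and aged males it was 100 of 100 (0, highest other 2091).

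A library far from the others of its group was found in 6 of 91 sets of a gene and a group, where 4.55 are expected by chance, all in young females. These were Ifi27l2a in cKO 2 (2013, nearest 1111), Isg15 in cKO 2 (1448, nearest 758), Cst6 in control 1 (25663, nearest 20155), S100a8 in control 1 (24.8, nearest 8.68), Oas1a in control 2 (331, nearest 189) and Csf1r in control 4 (744, nearest 575).

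The z test called a different cKO effect in young females and young males, with the difference of log2 changes female minus male, for Gch1 (1.40), Tifab (2.57), Fn1 (1.49), Krt1 (1.29), Bicd1 (2.35), Gpha2 (-3.13), Carns1 (-2.58), Cyp2g1 (-5.28), Sardh (-2.09) and Aldh3b2 (-0.87). None of these passed with Satterthwaite degrees of freedom (smallest adjusted p = 0.0914, Gpha2), and all but Tifab and Bicd1 did when the block for library numbers was added. Carns1 and Cyp2g1 were low in the male controls, as given above. Between young and aged females, young minus aged, the z test called Xist (10.28), Lrrc15 (5.44), Elovl6 (1.04), Gch1 (0.86), Krt71 (3.99), Slc39a2 (-3.42), Trpc2 (-7.99), Tgtp1 (-4.93, overlapping Gm12185) and Npbwr1 (-1.25). Of these, Xist, Slc39a2 and Trpc2 passed with Satterthwaite degrees of freedom. With the block added, Elovl6 and Krt71 also passed that t test (adjusted p = 0.0344 and 0.0313), where simulated unchanged tables gave 7 to 38 t calls.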

How the results depend on the processing

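Tests on counts (DESeq2, voom), count-based scaling factors and a joint fit of all tables were not run, because the values are not counts, nor was any alternative for heterozygous females, for which no per-library values were used here. The library-number block serves as the paired analysis, since the labels give no replicate numbers. With 2 or 3 libraries a group, fits that leave 1 out rest on the pooled spread, and a lone library is taken to vary like the others. Without counts, the effect of depth on low genes was not measured. The cause of a moved count was not tested unless a value is given.

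A set of 60 gene results holds Kdm6a in every table, the largest rises and falls under the naming rule, and the called list members of young females, so it is not the set of called named genes for which losses by library are given above. Of these under 421 alternatives, 368 kept their direction and side of the threshold, 53 kept the direction and lost the threshold, and 0 reversed. The losses were 30 on leaving out the library with the largest effect, 16 without the filter, 6 with quantile normalization and 1 with a pseudocount of 0.1. With the library-number block the calls were 2011 in young females, 7 in young males, 431 in aged females, 384 for the difference of young females and males, 227 for young and aged females, 43 for young and aged males, and 295 for the agreement of young and aged females, and all called named genes stayed called. Without the filter they were 1 in aged females, 46 and 2 for the differences between young and aged females and males, and 0 for the agreement. Quantile normalization gave 65 in aged females and 39 for the agreement, robust moderation 165 in aged females, and a threshold of 0.1 gave 215 for the agreement. In aged males 58 passed without the 3 libraries left out by their Gh, with 1 control left, whose muscle genes make up most of the falls. The t test with Satterthwaite degrees of freedom gave 0 for young females and males and 3 for young and aged females, and with the block 120, 7 and, for young and aged males, 1. With an estimated correlation 0 lists were called in young females, 0 in young males, 0 in aged females and 0 in aged males, and with fry 1, 0, 0 and 0.

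Leaving out 1 library gave 274 to 435 calls in young females, 1 to 3 in young males, 13 to 30 in aged females and 0 to 1 in aged males. For the differences it gave 20 to 129 between young females and males, 13 to 71 between young and aged females and 0 to 2 between young and aged males. Lists called ranged from 3 to 7 in young females and 4 to 14 in aged males.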

Other observations

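The tests by chromosome were chosen after the results were seen. Genes on the X chromosome were frequent among those that rose in young cKO females: 19 of 448 tested, against 6.97 expected (Fisher exact test, adjusted p = 0.00299). They were Efhc2 (log2 change 3.98), Gria3 (3.30), Dach2 (1.65), Kctd12b (1.54), Gspt2 (1.51), Dcaf12l1 (1.47), Ndp (1.45), Armcx6 (1.13), Renbp (1.10), Gprasp2 (1.05), Armcx2 (1.0), Fgf13 (0.99), Xlr (0.93), Reps2 (0.93), Prrg3 (0.73), Ap1s2 (0.68), Armcx1 (0.61), Armcx3 (0.52) and Maged1 (0.51). Armcx1, Armcx2, Armcx3 and Armcx6 are neighbouring paralogs. Ndp (16885521 to 16911774) and Efhc2 (17132049 to 17319368) lie near the deleted Kdm6a. The median log2 change of the 19 was 1.05 in young females and 1.01 in aged females (18 of 19 above 0). It was 0.60 in young males (13 of 15 measured) and, with the labels as given, 0.36 in aged males (16 of 17). The 19 genes were chosen in young females, so the value there is not an independent one. Both aged cKO female libraries lacked Xist (17.1 and 14.4), so X-linked changes there cannot be told apart from another difference of the X chromosome. Among fallen genes, chromosome 11 held 48 of 1174, against 28.3 expected (Fisher exact test, adjusted p = 0.00603).

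Snrpn and Snurf, which overlap, were mostly not both above 0 in a library. Exceptions were young male control 3 (26.8 and 40.0), young female control 2 (3.06 and 75.8), and aged female controls 5 (8.62 and 144) and 6 (5.77 and 142). In aged males Snrpn was 136, 112.1 and 90.7 in libraries labelled control and 0 in all 3 labelled cKO, and Snurf was 0 in the former and 123, 160 and 126 in the latter. Acta1, a skeletal muscle gene, was 5459 in the aged male library labelled control 4 and 52.5 to 227 in the other 5.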
